A study of Vitis vinifera with 6 samples.

How the data were processed

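Total RNA of 6 grapevine tissues was extracted by a modified CTAB method and made into small RNA libraries by the standard Illumina protocol, per the labels' protocols. The authors deposited, for each library, read counts per distinct sequence: 3 columns without a header with the length, the number of reads and the sequence. Adapters had been removed and identical reads collapsed, as the deposited files show. The tool and settings of trimming, any quality filter and any genome build are not given in the sources used here. Each file lists sequences of 18 to 44 nt, no sequence more than once, and the listed length matched the sequence in every row. The labels give 1 library per tissue and no replicate, and the stages and ages were taken from them. Sequencing of degraded mRNA, which the labels also mention, was not analysed here.

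Reads of 18 to 30 nt were kept, between 10672856 (flower) and 12142487 (mature leaf) per library, and at most 0.0642% of the reads of a library fell outside that range. Sequences read a single time made up between 79.5% (flower) and 81.1% (young leaf) of the distinct sequences. A count of 0 allows up to 3 reads, which is 0.25 RPM in mature leaf and 0.28 RPM in flower. Abundances are counts per 1000000 of these reads (RPM) with exact Poisson intervals, ratios have exact conditional binomial intervals, and shares have exact Clopper-Pearson intervals.

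A family's reads were the 19 to 24 nt sequences that hold positions 2 to 18 of any of its reference sequences. The 37 families and their references were written down before the data were examined, from general knowledge of conserved plant and grapevine microRNAs and of tasiR-ARF, not from a database, so a reference can be wrong. For 3 families it matched few reads or none, and 1 mismatch brought them to 10 RPM or more in some library. Of these, miR827 had at most 10 reads and miR3627 had 0 in any library. Allowing 1 mismatch gave miR827 between 238 RPM (young berry) and 1534 RPM (mature leaf) and miR3627 at most 22.8 RPM (young leaf). The third, miR845, had at most 26 reads in a library, and 1 mismatch gave it between 12.4 RPM (mature leaf) and 49.2 RPM (flower), with no call in any pair. The miR398 family had at most 7 reads in a library, and at most 0.61 RPM with 1 mismatch. A wrong reference cannot be told apart from a low level there. Copies of a family share reads and are given together. A RefSeq gene table for assembly ASM3070453v1 names 155 microRNA genes and has a locus for 33 of the 37 families; it served only to count loci, and no coordinates are given because the files name no build.

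The families were grouped before the data were examined into development (15), nutrient (7), silencing (3), phased-siRNA triggers (4) and other (8). The rule for naming, fixed at the same time, takes for each stage pair the 8 largest ratios in each direction among called families, the 6 most abundant families, all families set apart by organ up to 10, and in every pair miR156, miR172, miR397, miR398 and miR408. For sequences outside the families the rule needed a match to the nuclear genome and could not be applied, so none was named under it. A list's median was taken over the most abundant sequence of each measured family, with 0.5 reads added. It was set against 10000 random lists, in which each member was drawn from the 100 sequences nearest in mean expression among 27674 sequences outside the families, the set described next and the viroid stretch. Length was not matched, so a shift between size classes enters the percentile. The percentile describes these libraries.

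After the data were seen, sequences of 20 to 24 nt were collected that had at least 2 reads in each of 4 libraries, at least 10 in 1 of them, and in the missing 2 libraries together at most 1% of the highest count, for each choice of missing libraries. A 269-base stretch of hop stunt viroid, a small circular RNA pathogen common in grapevine, was written down from general knowledge, and reads identical to either strand were counted. Fragments of 5.8S ribosomal RNA and of an alanine tRNA were counted in the same way by a conserved stretch.

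The code of the caller was checked on simulated data that hold counting error alone and no variation between samples, so this says nothing of how tissues vary. With 200 sequences changed 3-fold it recovered 100% in each pair, with 0 false calls among 5422 unchanged sequences in the leaf pair, 5852 in the inflorescence and flower pair and 7696 in the berry pair, and the intervals held the simulated ratio in 95.0%, 95.2% and 95.8% of cases. Alternatives were scalings per 20 to 24 nt reads, by edgeR's TMM factors and DESeq2's size factors over the families, per reads of all families, and per these without miR166. Others were identical reads only, 1 mismatch, no minimum, a minimum of 100 RPM and a 4-fold threshold. For the reads per size class they were leaving out the families and counting distinct sequences, and for sequences outside the families a scaling per 20 to 24 nt reads and a minimum of 10 RPM. A scaling and counts without the set and the viroid stretch were added after the data were seen. Scaling by genome-matched reads was planned and not run. Python 3.11.15, scipy 1.17.1, numpy 2.4.6, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.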

Results

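Small RNAs were sequenced from 6 tissues of grapevine (Vitis vinifera), with 1 library per tissue. The tissues were a young leaf of 15 days, a mature leaf of 45 days, an inflorescence of 20 days, a flower at full flowering, a young berry of 20 days and a mature berry taken 15 days after veraison, the onset of ripening. They form 3 stage pairs, each an earlier and a later stage of leaf, of inflorescence and flower, and of berry. According to the series design, the tissues were chosen to follow how grapevine microRNAs and their targets vary during development; targets were not analysed here. The deposited read counts summed to 11046521 reads for young leaf, 12142844 for mature leaf, 12089689 for inflorescence, 10673047 for flower, 11486660 for young berry and 11456615 for mature berry. With no replicate in any tissue, the tissues were not tested against each other, no p-value is given, and each difference is one between 2 libraries. All intervals are 95% intervals that cover counting error only, and reads without molecular identifiers are not independent molecules. Abundance is given as reads per 1000000 reads of 18 to 30 nt (RPM). A family was called higher or lower where it reached 10 RPM in at least 1 of the 2 libraries, differed by 2-fold or more and had a counting interval of the ratio that excluded 1.

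The first question was how the size classes of small RNA were balanced in each tissue. In plants, 21 nt reads come mostly from microRNAs and phased siRNAs, and 24 nt reads mostly from siRNAs that guide DNA methylation. The 21 nt class made up 41.5% of reads in young leaf and 49.9% in mature leaf, 37.4% in inflorescence and 31.0% in flower, and 38.2% in young berry and 52.4% in mature berry. The 24 nt class was larger than the 21 nt class in flower and, by little, in inflorescence and young berry. It made up 50.9% of reads in flower against 39.7% in inflorescence. It was smaller in the later stage of the other pairs, at 23.1% in mature leaf against 35.0% in young leaf and 24.9% in mature berry against 39.5% in young berry. Exact Clopper-Pearson intervals of these shares were at most 0.060 percentage points wide. The number of 24 nt reads per 21 nt read was 1.64 in flower, 1.06 in inflorescence and 1.03 in young berry. It was 0.84 in young leaf, 0.48 in mature berry and 0.46 in mature leaf. Distinct sequences moved the same way as reads in each pair, though by less. Among them, 24 nt sequences made up 69.2% in flower against 67.2% in inflorescence, and 52.6% in mature leaf against 62.4% in young leaf. Set beside these shares, 19.9% of the mature berry reads and 4.21% of the young berry reads belonged to a set of mostly 20 to 22 nt sequences that was nearly missing from young leaf and flower. Without that set and without reads of a viroid stretch, a choice made after the data were seen, the 21 nt share of mature berry exceeded that of young berry by 6.89 percentage points in place of 14.1. In the leaf pair, a single 21 nt sequence outside the families was at 15914 RPM in young leaf and 67180 RPM in mature leaf. Part of the higher 21 nt share of mature leaf is thus reads of that sequence, and the shares were not counted without it.

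**Figure D1:**
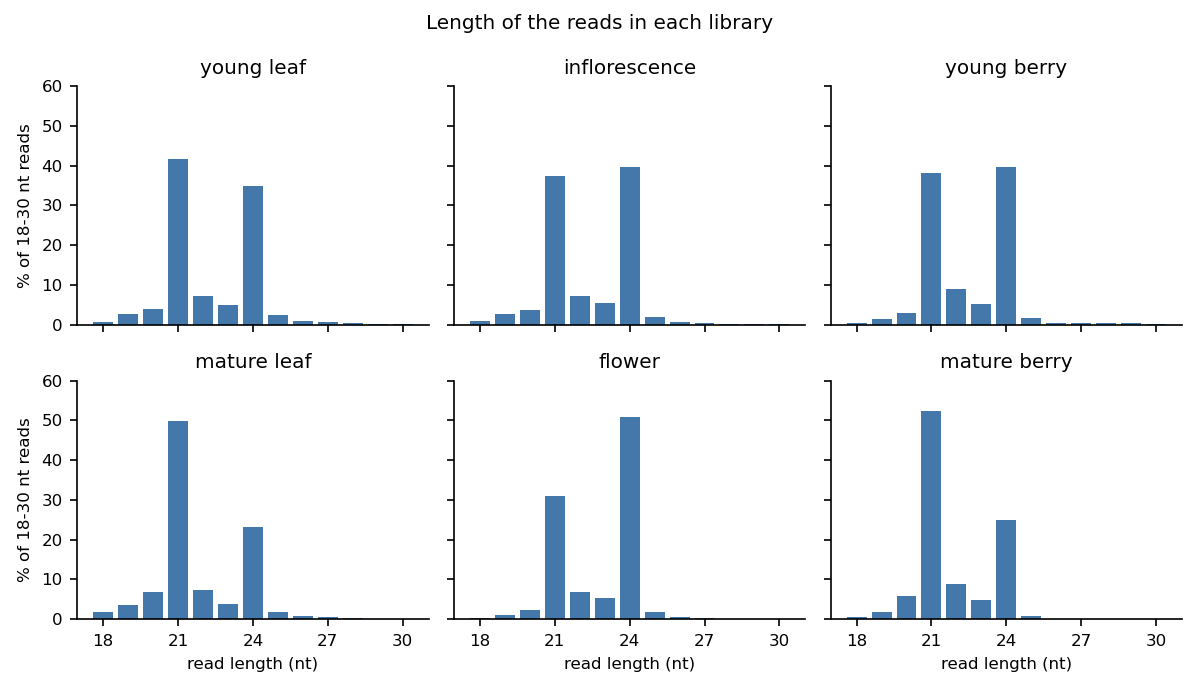
Percent of the 18 to 30 nt reads (vertical axis) at each read length in nt (horizontal axis), as one bar per length in each of the 6 libraries. The 21 nt bar is the tallest in both leaf libraries and in mature berry (52.4%), and the 24 nt bar in inflorescence, in flower (50.9%) and in young berry.

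The families followed here, 37 in number, took 13.9% of the reads in young leaf, 7.36% in mature leaf, 7.28% in inflorescence, 5.61% in flower, 5.31% in young berry and 4.25% in mature berry. The miR166 family, which targets HD-ZIP III transcription factors, was the most abundant of them and held between 52.3% (mature leaf) and 84.4% (young leaf) of all family reads.

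Between young and mature leaf, regulators of leaf development differed in both directions. The miR166 family was 3.04-fold lower in mature leaf (interval 3.03 to 3.05), at 38497 RPM against 116951 RPM. The miR390 family, which cuts the TAS3 transcripts that yield the tasiR-ARF siRNAs, was 3.63-fold lower (3.43 to 3.85), while tasiR-ARF itself stood at 1572 RPM in young leaf and 1403 RPM in mature leaf and was not called. With only reads identical to a reference, which are a small part of its reads, tasiR-ARF was 5.31-fold lower in mature leaf (4.66 to 6.06), at 22.8 RPM against 121 RPM. Higher in mature leaf were miR164, which targets NAC factors of the CUC class, by 3.51-fold (3.41 to 3.62), and miR396, which targets the GRF growth factors, by 3.40-fold (3.10 to 3.74). Of the 27 families that reached 10 RPM, 8 were higher in mature leaf, 4 were lower and 15 were neither.

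Among the 15 families of the development list, 13 reached the minimum, 6 were higher in mature leaf and 2 were lower. The other 4 higher ones were miR394 by 5.50-fold (4.19 to 7.32), or 8.44-fold (5.97 to 12.3) with identical reads alone, miR160 by 3.84-fold (2.96 to 5.05), miR169 by 2.10-fold (1.96 to 2.26) and miR167 by 2.06-fold (2.04 to 2.07). With identical reads alone miR159 was also called, 2.21-fold higher (2.07 to 2.37). The miR160 and miR167 families target auxin response factors, miR169 targets NF-YA factors and miR394 an F-box gene. The age-marking families were not called, with miR156, which targets SPL factors, at 5588 and 10002 RPM and miR172, which targets AP2-type factors, at 1514 and 1747 RPM in young and mature leaf. No member of the nutrient list was called, with 4 of its 7 families above the minimum, but this depended on the rule for a family's reads. The reference of miR827 did not match, and with 1 mismatch allowed miR827 was 2.11-fold higher in mature leaf (2.06 to 2.17). With identical reads alone miR399 was 3.51-fold higher (2.60 to 4.79). Of the copper families, miR397 was at 9.15 RPM in young and 12.7 RPM in mature leaf, miR408 at 2.36 and 3.79 RPM and miR398 at 0.18 and 0.58 RPM, the last 2 below the minimum. All 3 silencing families were measured and none was called, and miR168, which targets AGO1, was at 2450 and 3585 RPM. Of the 4 families that trigger phased siRNAs, 3 were measured, and miR482, which targets NB-LRR resistance genes, was 2.72-fold lower in mature leaf (2.55 to 2.90). Among the other families miR3624 was 6.52-fold higher (5.69 to 7.49), miR535 3.17-fold higher (3.07 to 3.28) and miR3634 3.11-fold lower (2.71 to 3.58). The reference of miR3627 did not match, and with 1 mismatch allowed miR3627 was 4.62-fold lower (3.47 to 6.23), at 4.94 RPM against 22.8 RPM.

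The median log2 ratio of the main sequences of the development list, mature over young leaf, was 1.03. This was at percentile 99.9 among 10000 random lists of the same size matched on mean expression, not on length. The medians of the nutrient, silencing, phased-siRNA trigger and remaining lists were -0.0049 (percentile 43.2), 0.36 (57.1), -0.53 (11.3) and 0.47 (68.2). Reads of 5.8S ribosomal RNA, one sign of RNA breakdown, were at 4908 RPM in young leaf and 5978 RPM in mature leaf, and those of an alanine tRNA at 28803 and 17994 RPM. The split of calls depended on the scaling: per reads of all families 16 were higher and 0 lower, with edgeR's TMM factors 6 and 7, with DESeq2's size factors 6 and 6, and per family reads without miR166 5 and 7. The calls of miR167 and miR169 ended under the last 3 of these, that of miR535 under the last, and those of miR166, miR390, miR482 and miR3634 under the first. Per reads of all families, miR156 (3.37-fold), miR172 (2.17-fold), miR168 (2.76-fold), miR397 (2.61-fold), miR399, miR159, miR403 and miR858 were also called higher. The families miR479 and miR2111 were called lower with TMM, with DESeq2's size factors and per family reads without miR166, and miR3633 under the first and last of these 3.

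Inflorescence and flower were the most alike of all library pairs, with a median absolute log2 difference of 0.42 over 30 families. Only miR535 was higher in flower, by 2.29-fold (2.19 to 2.40). Lower in flower were miR858, which targets R2R3-MYB genes, by 3.00-fold (2.45 to 3.68), and miR399, which targets the PHO2 gene of phosphate signalling, by 2.65-fold (1.92 to 3.71), at 4.78 RPM against 12.7 RPM. With identical reads alone miR399 fell under the minimum, with a ratio of 3.83-fold lower in flower (1.05 to 20.9). The remaining 23 of the 26 measured families were neither.

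None of the 12 measured development families was called on the scale of all reads. Inflorescence and flower values were 46392 and 34072 RPM for miR166, 11643 and 7233 RPM for miR156, 7366 and 6251 RPM for miR167, 75.7 and 57.4 RPM for miR172, and 846 and 1413 RPM for tasiR-ARF. In the nutrient list 1 of 4 measured families, miR399, was lower. Its copper members were at 8.02 and 14.1 RPM (miR397), 1.90 and 2.34 RPM (miR408) and 0.17 and 0.09 RPM (miR398). None of the 3 silencing families was called, with miR168 at 3165 and 3606 RPM. In the trigger list 1 of 3 measured families, miR858, was lower, and in the remaining list 1 of 4, miR535, was higher, while miR479 stood at 531 and 994 RPM. List medians of the log2 ratio, flower over inflorescence, were -0.45 for development (percentile 5.72 of random lists), -0.27 for nutrient (11.2), 0.08 for silencing (49.1), -0.32 for triggers (17.8) and 0.46 for the rest (73.1). The 5.8S ribosomal reads were at 3571 RPM in inflorescence and 1833 RPM in flower, and those of the alanine tRNA at 16119 and 5473 RPM. The set of sequences nearly missing from young leaf and flower took 3.75% of the inflorescence reads and 0.0057% of the flower reads. With edgeR's TMM factors 4 families were higher in flower and 2 lower, as also per reads of all families and per family reads without miR166, and with DESeq2's size factors 3 and 2. The families added under the first 3 were tasiR-ARF (2.01-fold, 2.17-fold and 2.00-fold), miR397 and miR479, and with the size factors miR397 and miR479.

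Young and mature berry differed most among the stage pairs, with a median absolute log2 difference of 1.41. By this measure the libraries did not group by organ in leaf or berry. Mature berry was nearer to flower (0.88) and to inflorescence (1.23) than to young berry. Young leaf was nearer to flower (0.59) than to mature leaf (0.81). The miR390 family was at 241 RPM in young berry and 1.75 RPM in mature berry, 138-fold lower (89.4 to 227), and the tasiR-ARF siRNAs that follow from its cut were 24.2-fold lower (21.4 to 27.5), at 22.9 RPM against 553 RPM. The size of both depended on the rule for a family's reads: miR390 was 39.6-fold lower (31.9 to 49.7) with 1 mismatch allowed, and tasiR-ARF 120-fold lower (21.1 to 4768) with identical reads alone. The miR164 family was 23.1-fold lower (21.2 to 25.3), at 45.3 RPM against 1048 RPM. Higher in mature berry were families of the nutrient list, namely miR408, a copper family that targets plantacyanin and laccases, by 7.42-fold (5.20 to 10.9), miR2111 by 5.02-fold (3.97 to 6.43) and the phosphate family miR399 by 4.09-fold (3.36 to 5.01). Of the 28 measured families 7 were higher in mature berry, 11 lower and 10 neither.

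In the development list 12 families were measured, 5 lower and 2 higher. Besides those above, miR171, which targets SCL factors, was 5.17-fold lower (4.21 to 6.41) and miR167 2.61-fold lower (2.55 to 2.67). The miR167 call ended with DESeq2's size factors, and with only reads identical to a reference its log2 ratio was 0.023, with an interval of the ratio, 0.98 to 1.06, that held 1. Higher were miR156 by 2.62-fold (2.58 to 2.65), at 7700 RPM against 2943 RPM, and miR319, which targets TCP factors, by 3.12-fold (2.37 to 4.15). With only reads identical to a reference, the log2 ratio of miR319 was -3.17, the other direction, at 0.78 RPM in young and 0.087 RPM in mature berry, below the minimum. The miR172 family was at 198 RPM in young and 187 RPM in mature berry, and miR166 at 36237 and 25624 RPM, neither of them called. With identical reads alone miR172 was 2.18-fold higher in mature berry (2.00 to 2.39), and the log2 ratio of miR166 was 0.16 in place of -0.50.

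The nutrient list had 5 measured families, 3 higher and 1 lower, the latter being the copper family miR397, which targets laccases, by 2.70-fold (2.10 to 3.50). With DESeq2's size factors the miR397 call ended, and with only reads identical to a reference miR399 fell under the minimum, at 0.61 and 0.79 RPM. The third copper family, miR398, was at 0.35 and 0.61 RPM, below the minimum. All 3 measured trigger families were lower in mature berry, namely miR482 by 4.76-fold (4.33 to 5.24), miR858 by 3.85-fold (3.13 to 4.77) and miR3633 by 2.03-fold (1.76 to 2.35). The naming rule did not take miR3633 or miR162, which targets DCL1 and was the 1 of 3 silencing families called, 2.16-fold lower (2.07 to 2.26). Both are given to complete the counts, and both calls ended with the TMM factors, with the size factors, per reads of all families and per reads outside the 20 to 22 nt set and the viroid stretch. The miR3633 call also ended with 1 mismatch allowed (1.99-fold) and held in 2 of 7 other scalings and read rules, no berry read being identical to its reference. The most abundant silencing family, miR168, was at 4532 and 3047 RPM. Among the other families miR477 was 7.52-fold higher (4.70 to 12.7), though no read was identical to its reference, miR3624 5.56-fold higher (5.16 to 5.99) and miR3634 5.50-fold lower (4.27 to 7.17), while miR479 was at 3243 and 3046 RPM and miR535 at 543 and 766 RPM.

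The nutrient list had a median log2 ratio, mature over young berry, of 2.27 (percentile 99.98 of random lists). This median leaves out miR827, whose reference did not match. With 1 mismatch allowed miR827 was at 238 RPM in young and 451 RPM in mature berry, 1.90-fold higher (1.81 to 1.99) and not called. The median was not taken with miR827 in it. Medians were -0.57 for development (1.82), -0.57 for silencing (14.2), -2.02 for triggers (2.32) and 0.52 for the rest (71.0). The 5.8S ribosomal reads were at 858 RPM in young and 1105 RPM in mature berry, and those of the alanine tRNA at 8387 and 6931 RPM. Scaled per reads outside the set that filled 19.9% of mature berry and outside the viroid stretch, 7 families were higher and 9 lower. With DESeq2's size factors 9 were higher, miR395 and miR535 among them, and 7 lower.

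**Figure D2:**
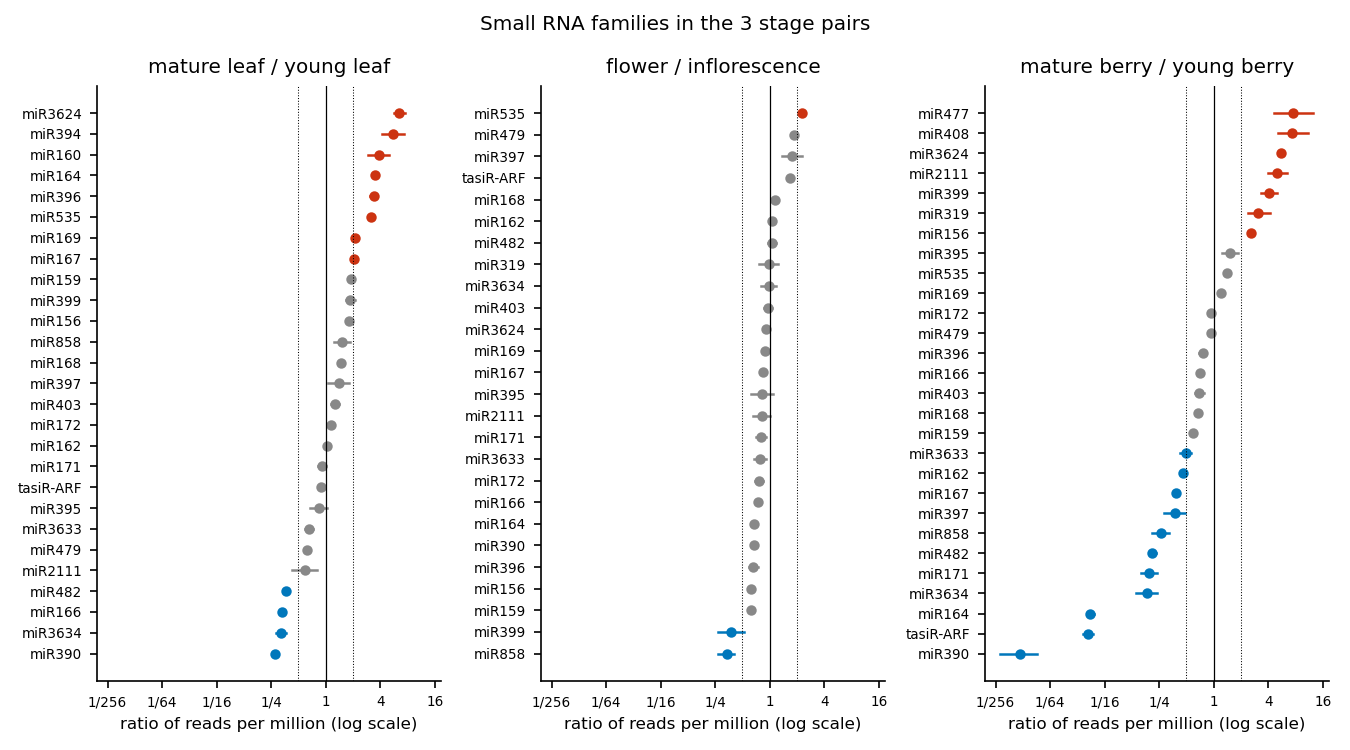
Ratio of RPM, later over earlier stage (horizontal axis, log scale), of each family (vertical axis) that reached 10 RPM in 1 of the 2 libraries, for the 3 stage pairs. Points are ratios and bars 95% exact intervals for counting error only, red for families called higher in the later stage, blue for those called lower and grey for neither, with dotted lines at 2-fold. The berry panel has the widest spread, down to miR390 at 138-fold lower in mature berry.

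Families that set an organ apart were sought by asking whether both libraries of an organ lay 2-fold or more above, or below, all 4 other libraries. Of the 30 families that reached 10 RPM in some library, miR172 was the one set above, at 1514 and 1747 RPM in the leaves and at most 198 RPM elsewhere, a gap of 7.65-fold. It was also set below in inflorescence and flower, at 75.7 and 57.4 RPM. The miR167 family was set below in the berries, at 2066 and 791 RPM against at least 5959 RPM elsewhere. In the leaves miR319 was set below, at 1.27 and 1.65 RPM, and in inflorescence and flower miR477, at 0.17 and 0.28 RPM, which is 2 and 3 reads. The order alone, with no fold limit, held in 8 cases above and 8 below, where chance ordering gives 6 of each, since the pair of an organ takes the top places in 6.67% of orders. The miR172 leaf case held under every scaling and with identical reads alone. The others did not all hold: miR167 was no longer set below per reads of all families, nor miR477, and with identical reads alone only miR167 of the 4 cases below was left.

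Reads outside the families were compared as distinct 20 to 24 nt sequences that reached 50 RPM in 1 library of a pair and differed 4-fold or more. Between the leaves 1228 sequences were measured, 108 higher in mature leaf, of which 88 were 21 nt long, and 53 lower. Between inflorescence and flower 1378 were measured, 186 higher in flower, of which 155 were 24 nt long, and 125 lower, of which 90 were 21 nt long. This balance turned at a minimum of 10 RPM, where more sequences were lower than higher in flower. Between the berries 2211 were measured, 742 higher in mature berry, of which 610 were 21 nt long, and 132 lower. Of these, 583 of the 742 sequences higher in mature berry, 84 of the 125 lower in flower and 38 of the 108 higher in mature leaf belonged to the set nearly missing from young leaf and flower, and 24 of the 186 higher in flower matched the viroid stretch. Without both groups the counts were 153 higher in mature berry, 41 lower in flower, 69 higher in mature leaf and 162 higher in flower. The genomic origin of the reads was not analysed here, because no genome sequence was used.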

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

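All tests of explanations in this part were chosen after the result was seen.

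The miR164 and miR167 families were called in opposite directions in leaf and berry. The log2 ratio of mature over young tissue in leaf exceeded that in berry by 6.35 for miR164 and by 2.42 for miR167. With 1 library per tissue, these differences were not tested. The miR164 calls held under all 8 other scalings and read rules, with differences from 5.43 to 6.94. The miR167 calls did not: the leaf call ended under 3 of the 8 and the berry call under 2, and with identical reads alone the log2 ratios were 1.07 in leaf and 0.023 in berry, a difference of 1.05.

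A set of 11945 distinct sequences, mostly 20 to 22 nt long, was read in mature leaf, inflorescence, young berry and mature berry and nearly missing from young leaf and flower. It took 19.9% of the reads in mature berry, 4.21% in young berry, 3.75% in inflorescence and 2.95% in mature leaf, but 0.0053% in young leaf and 0.0057% in flower. For each of the other 14 choices of 2 missing libraries there were at most 2769 such sequences. Even spill-over of reads from the mature berry library, as the only source, would give every sequence the same ratio to mature berry. The ratios varied far more than counting error, as the chi-square per degree of freedom was at least 21.8 in the other 3 libraries. Reads are not independent molecules and no other sequences were measured this way. Uneven spill-over, or spill-over beside reads of the tissue, is therefore not excluded. Double-stranded coding RNA of another organism or agent, such as a virus, may be the source. Joined by shared stretches of 14 bases, the set gave 33 joined stretches of 100 bases or more. They held 4337 bases, the longest 235. Of these 33, 29 had a reading frame without stop codons, against at most 25 in 1000 shuffles. Shorter stretches were not examined, and no other sequences were joined for comparison. Of the 20 to 22 nt sequences, 68.7% overlapped the opposite strand of another, against 31.8% of comparison sequences. The comparison was a random draw searched only within itself, which can lose partners left undrawn, so it cannot decide for a double-stranded source. Plant coding genes also have open frames and no genome was used, so the source stays open, and organ or stage cannot be told apart from the individual plants sampled, since each tissue has 1 library (3.75% in inflorescence).

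Reads identical to the hop stunt viroid stretch made up 1.10% of the flower library and 1.07% of the mature berry library. In the other libraries they made up between 0.36% (inflorescence) and 0.54% (young berry).

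In mature berry miR390, tasiR-ARF and miR164 were far lower than in young berry. Dilution by the set and the viroid reads is too small to account for it, as arithmetic and not as a test. Scaling per reads outside both shifts every log2 ratio of the pair by 0.27. The log2 ratio nearest 0 among the 3 families was then still -4.26. An even loss of microRNAs would leave hardly any family higher, and 7 families were called higher, against 11 lower. RPM are relative, so a loss of all small RNAs alike would not show, and a general fall beside some rises is not excluded. The families together took 5.31% of reads in young berry and 4.25% in mature berry. Selective loss of some sequences and the ripening stage itself stay open and were not tested.

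The 21 nt share was 14.1 percentage points higher in mature than in young berry. The set as collected and the reads identical to the viroid stretch are not the whole cause, since 6.89 points were left without them. Nor are the microRNA families, without which the difference was 15.4 points. The set may account for the part that went with it. It holds only sequences that passed its read limits, so reads of the same source outside it may be among the rest. That and the berry stage stay open for the rest as untested.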

How the results depend on the processing

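The settings without the set and the viroid stretch were chosen after the data were seen. Called families gave 262 values under other scalings and read rules, a family with no reads in 1 library giving none; 237 of them stayed 2-fold or more in the same direction and 2 took the other sign, both in mature against young berry with only reads identical to a reference: miR167 with a log2 ratio of 0.023, which is no difference within its counting interval, and miR319 with -3.17. In miR167, the main 21 nt member identical to a reference was at 413 RPM in young and 419 RPM in mature berry. Other abundant members were lower in mature berry, the main 22 nt member at 690 and 184 RPM and another 21 nt member at 762 and 121.5 RPM. Some minor members were higher, one of 22 nt at 7.23 and 26.3 RPM. In miR319, a member not identical to a reference had 27 and 194 reads. Both calls thus rest on members that the identical rule leaves out. Why members differed was not tested. The scalings shift all log2 ratios of a pair alike: in the leaf pair by -0.59 (TMM), -0.38 (DESeq2), 0.91 (reads of all families) and -0.70 (the same without miR166), in flower over inflorescence by 0.27, 0.24, 0.38 and 0.26, and in the berry pair by 0.31, 0.54, 0.32 and -0.0005, with 0.27 in the berry pair without the set and the viroid stretch. Other shifts were under 0.1. Each count of families below moved for that reason where a scaling is named, and through fewer families where a limit is named.

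Families higher in mature than in young leaf, 8 as reported, were 16 per reads of all families, 5 per these without miR166 and 2 at 4-fold. Those lower, 4, were 7 with TMM, 0 per reads of all families, 7 without miR166 and 0 at 4-fold. Families higher in flower, 1, were 4 with TMM, 3 with DESeq2's size factors, 4 per reads of all families, 4 without miR166 and 0 at 4-fold, and those lower, 2, were 1 with identical reads, 0 at 100 RPM and 0 at 4-fold. Families higher in mature berry, 7, were 2 at 100 RPM, and those lower, 11, were 7 with DESeq2's size factors, 6 at 100 RPM and 6 at 4-fold. Families set above by an organ, 1, were 4 per reads of all families, 3 without miR166, 2 without the set and the viroid stretch and 2 with identical reads, and those set below, 4, were 2 per reads of all families and 1 with identical reads.

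The differences in size class kept their direction throughout. For 21 nt reads, mature minus young leaf was 14.1 points without the families, 6.65 for distinct sequences and 7.18 without the set and the viroid stretch (8.36 as reported). Flower minus inflorescence was -5.71, -1.04 and -4.50 (-6.41 as reported), and mature minus young berry 15.4, 5.12 and 6.89 (14.1 as reported). For 24 nt reads the same 3 settings gave -15.7, -9.83 and -11.2 for the leaves (-11.9 as reported), 11.1, 2.01 and 9.64 for flower minus inflorescence (11.2 as reported) and -15.7, -8.12 and -10.2 for the berries (-14.6 as reported). The cause of each was not tested beyond what was left out. No setting left out the single 21 nt sequence at 15914 RPM in young leaf and 67180 RPM in mature leaf. Among distinct sequences it counts only once, and there the leaf difference was 6.65 points.

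Sequences outside the families at a minimum of 10 RPM, where more are measured, numbered 989 higher and 303 lower in mature leaf, 674 higher and 992 lower in flower, and 2769 higher and 952 lower in mature berry. In flower the balance thus turned from the reported 186 higher and 125 lower. At the reported minimum of 50 RPM but without the set and the viroid stretch, 69 were higher in mature leaf, 41 lower in flower and 153 higher in mature berry (108, 125 and 742 as reported). Scaling by genome-matched reads was not run. A fit of stage with the 3 organs as blocks was not run. The minimum of 10 RPM alone barred 3 cases that passed the other limits, miR828 in the leaf pair (3.18-fold higher in mature leaf, 1.64 to 6.64) and miR160 (2.93-fold higher in mature berry, 1.86 to 4.77) and miR530 (2.86-fold lower, 1.56 to 5.54) in the berry pair. For miR398, with 7 reads at most in a library, the interval held 1 in each pair.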

Other observations

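Everything in this part was chosen after the values were seen. The make-up of some families differed between libraries, both across organs and between the stages of the berry. Of the miR167 reads, the sequence TGAAGCTGCCAGCATGATCTC made up 33.6% in inflorescence (95% Clopper-Pearson interval 33.3 to 33.9%), 40.6% in flower (40.3 to 41.0%) and 36.9% in young berry (36.3 to 37.5%). It made up 15.4% in mature berry (14.6 to 16.1%), 1.40% in young leaf (1.31 to 1.49%) and 0.77% in mature leaf (0.73 to 0.82%). Of the miR166 reads, TCGGACCAGGCTTCATTCCTC made up 42.7% in young berry (42.5 to 42.8%) and 12.5% in mature berry (12.4 to 12.6%). The higher level of miR156 in mature berry was not shared by TTGACAGAAGAGAGGGAGCAC, which made up 1.61% of miR156 reads in young berry (1.48 to 1.75%) and 0.011% in mature berry (0.0054 to 0.021%), and 10.9% in flower (10.7 to 11.1%). The sequence AGAATCTTGATGATGCTGCAT made up 97.2% of the miR172 reads in young leaf (96.9 to 97.4%), 29.8% in young berry (28.0 to 31.8%) and 71.0% in mature berry (69.0 to 72.9%). These shares lie within a family and do not depend on the scaling.

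Several abundant 21 nt sequences outside the families differed widely between libraries. Their place in the genome was not determined. TGAGTAGTGGACTATCGCATG was at 2101 RPM in inflorescence and 1532 RPM in flower, and at most 14.2 RPM (young berry) elsewhere. CCAGGTACTGTGCAACGTCAT was at 2719 RPM in inflorescence, 3041 RPM in flower, 1058 RPM in young berry and 4140 RPM in mature berry, against 2.17 RPM in young leaf and 4.36 RPM in mature leaf. In the other direction, TAAGAAGACTAAGCTCAGGAT was at 9738 RPM in young leaf and 5234 RPM in mature leaf, at 403 and 421 RPM in inflorescence and flower, and at 36.1 and 1.66 RPM in young and mature berry. The sequence TGAAGGTCCGAGGTAGAGGCA alone held 67180 RPM in mature leaf, more than the miR166 family there. It was at 15914 RPM in young leaf, 18298 RPM in inflorescence, 6221 RPM in flower, 2106 RPM in young berry and 127 RPM in mature berry, and so did not follow organ. The grapevine microRNA miR2950, TTCCATCTCTTGCACACTGGA, was not among the families fixed beforehand and was at 804 RPM in inflorescence and 941 RPM in flower, against 31.4 RPM in young leaf, 13.1 RPM in mature leaf, 130 RPM in young berry and 114 RPM in mature berry.

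Reads of the hop stunt viroid stretch were present in all 6 libraries, from 0.36% of reads in inflorescence to 1.10% in flower, on both strands and over at least 241 of the 269 bases. Of these reads, 45.9% were 24 nt long in flower, against between 17.3% (young berry) and 22.9% (mature berry) in the other libraries. Flower was also highest among all reads of 18 to 30 nt, with 50.9% at 24 nt. The other libraries had between 23.1% (mature leaf) and 39.7% (inflorescence). Reads of 24 nt from the stretch were at 5046 RPM in flower and 827 RPM in inflorescence, and those of 21 nt at 4341 and 2182 RPM.

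Reads starting with T made up 64.3% of 21 nt reads in young leaf and 42.7% in mature berry, and reads starting with A made up 53.0% of 24 nt reads in young leaf and 32.6% in mature berry. Young berry lay between them, at 54.8% and 44.7%. The set of mostly 20 to 22 nt sequences took 19.9% of the mature berry reads, and first bases were not counted without it.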
